A study of Mus musculus with 76 samples.

How the data were processed

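RNA was measured in 76 tumours of C57BL/6 mice. Per the labels, total RNA was extracted with a Qiagen RNeasy kit, biotinylated cRNA was prepared by the standard Affymetrix protocol, and each tumour was put on 1 array of 45101 probe sets. The deposited values are on the log2 scale, from 1.77 to 14.18, with 1 value for each probe set and array. The submitters' processing notes name affy, without a version. The method of background correction, normalization and summarisation is not given in the sources used here. The lower quartiles of the arrays lay between 3.70 and 3.92 and the upper quartiles between 7.60 and 7.81, so the values had been normalized between arrays by the authors, and they were used as deposited. No per-sample column of values was left unused, and 0 arrays were identical.

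Arrays were grouped by the introduced gene of the directed complementation model, and the label T1, T2 or T3 was kept as a second factor. Of the probe sets, 34958 name 1 gene, 932 name several and 9211 have none listed. For 34754 of them the gene was found in the annotation of the mouse assembly GRCm38.p6, with 0 symbols changed; the assembly was used for names, positions and which genes share a chromosome. Each of 18194 genes was represented by its probe set with the highest mean. A gene was tested if that probe set lay above the 40th percentile of its array in at least 4 arrays, which left 13868 genes. The background level is the median of 3 control probe sets against a bacterial trp gene (2.95).

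All arrays were fitted together by limma (3.58.1, with statmod 1.5.0, and data.table version 1.17.8, in R 4.3.3) with the introduced gene and the T label as terms, which left 61 residual degrees of freedom. Moderated statistics were two-sided and adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. MAP3K11 was compared with the equally weighted mean of the other 12 groups, with MAP3K7 and with HER2, MAP3K7 with HER2, FGFR2aIIIb with FGFR2aIIIc, RONd160 with RON+MSP, and T2 and T3 with T1. An F test covered the 13 groups. A random block for arrays of 1 introduced gene and 1 T label had been planned, to be left out if its correlation was 0 or below; the estimate was -0.31, so no block was used. Fitted differences are adjusted for the T label, so they can depart slightly from the difference of the means.

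Tests on gene lists used camera with a preset correlation between genes of 0.01, and again with the correlation estimated for each list, adjusted over the 30 lists of a comparison. The lists were fixed from general knowledge of pathways and cell types and named 700 members, of which 596 were measured, 5 to 34 for each list. A list's members were also counted with their p-values adjusted over the list alone. By fry, which tests a list without setting it against other genes, 8 of the 8 lists called for MAP3K11 against the other groups were called, and 6 of 9, 10 of 11, 10 of 10, 0 of 6 and 4 of 12 in the other comparisons of groups, in their order above. The named genes are the 10 with the highest and the 10 with the lowest difference among called genes in which every array of the first group lay on 1 side of the mean of the comparison group. This rule was used for MAP3K11 against the other groups and against MAP3K7, and 5 in each direction were taken for the other comparisons. In each list called by camera, up to 4 called members with the largest difference in the list's direction were added. The introduced genes were named too. Groups, comparisons, lists, the rule and the alternatives were chosen before the data were examined, except where the text says otherwise. The gene in the series title is not reported here.

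The alternatives changed 1 choice at a time: the block, means for each introduced gene and T label, the T term, the replicate number as a block, the filter, quantile normalization or median centring of the arrays, the probe sets that stand for a gene, the variance prior, array weights, the threshold, the arrays in the fit and leaving out each replicate or group. Of those chosen after the data were seen, the first takes pairs of arrays as a random block. Within each group the arrays were matched into pairs by the Pearson correlation of their 19 autosome medians over 13420 genes, and the correlation within the 38 pairs was estimated at 0.628. In all 38 pairs the T labels differ, so the planned block and its estimate of -0.31 could not take up this correlation. The second adds the skeletal muscle list's mean as a covariate, and the third leaves out 2 MAP3K7 arrays. In data simulated with the measured spread and independent arrays, which leaves the pairs out, 93 of 100 genes changed by 1 log2 unit were recovered for MAP3K11 against the other groups, and 90 against MAP3K7. With noise correlated within the pairs and no true change, the 6 comparisons of groups gave 132 to 159 false calls with arrays as replicates, and limma called 0 with the pairs as a block. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision, and the labels do not say which arrays came from 1 tumour line or animal.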

Results

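Gene expression was measured in 76 mouse tumours, with 1 Affymetrix array for each. The tumours came from a directed complementation model. In it, a tumour that grows on a doxycycline-inducible mutant form of the receptor kinase HER2 loses that driver when doxycycline is withdrawn, and a gene introduced in its place is asked to keep it growing. The labels name 13 introduced genes, and the arrays were grouped by them. ErbB3, FGFR2aIIIb, FGFR2aIIIc, FGFR3, HER2, RON+MSP and RONd160 are forms of receptor tyrosine kinases, RON+MSP being a receptor with its ligand. FAK1, TNK2 and RSK2 are intracellular kinases, PIP5K1B is a lipid kinase, and MAP3K7 (TAK1) and MAP3K11 (MLK3) stand at the head of MAP kinase cascades. FAK1 had 4 arrays and each of the other 12 groups had 6. The 6 MAP3K11 arrays are labelled as tumours with cachexia, the wasting of body tissue in cancer, and the other 70 arrays as tumours without it. Each array also carries a label T1, T2 or T3, which the labels do not define. They call the arrays biological replicates but do not say which animals or tumour lines they came from, so the p-values measure the spread between these arrays, which may be partly technical.

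Values were on the log2 scale, and array medians lay between 5.45 and 5.56. Control probe sets against a bacterial trp gene, which has no mouse target, had a median of 2.95. Where a group's mean lay at or below this level, the difference is limited by background. The number of arrays limits the precision. Within a group the arrays fell into pairs. Matched on the median expression of each autosome, the 38 pairs had a median Pearson r across chromosomes of 0.956, against 0.170 between other arrays of the same group and -0.03 between arrays of different groups, a difference that the matching favours. The highest value between arrays of different groups was 0.937. Expression with the chromosome medians removed, which was not matched on, correlated at a median of 0.773 within these pairs and 0.270 between other arrays of the same group. In 38 of the 38 pairs the arrays carried different T labels. Because paired arrays resembled each other beyond their group, the count of genes called in each comparison is also given with these pairs as a random block, an alternative chosen after seeing the data. Unless stated, the SEs and p-values are from the fit without that block, which counts paired arrays as separate.

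**Figure D1:**
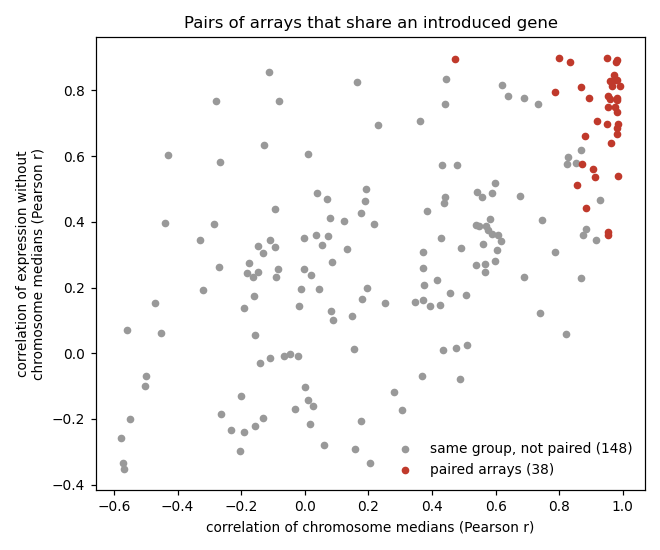
Each point is a pair of arrays of one introduced gene. The x axis is the Pearson correlation of their 19 chromosome medians and the y axis that of their expression after the chromosome medians were removed; the 38 matched pairs (red) lie to the upper right of most of the other 148 (grey).

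The first question was how far expression differed between the groups of the introduced genes. Of 13868 genes tested, 11916 (85.9%) differed among the 13 groups by limma's F test, and 7495 with the pairs as a block. The labels do not give the tumour lines, so an effect of the introduced gene cannot be told apart from differences between lines. Set against the mean of the other 12 groups, MAP3K11 differed in 7521 genes (5455 with the pairs as a block). ErbB3 followed with 3961 (1653 with the block), HER2 with 3690 (1324), MAP3K7 with 3390 (1096) and RONd160 with 3232 (1211). PIP5K1B differed in 2593 genes, RSK2 in 2530, FGFR2aIIIb in 1646, RON+MSP in 1189, FAK1 in 1168, TNK2 in 716, FGFR3 in 360 and FGFR2aIIIc in 224. With the block these 8 counts were 501, 359, 265, 64, 112, 13, 0 and 10; for FGFR3, the 0 is by limma, with 1126 genes at an unadjusted p under 0.05.

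The mouse probe sets of the introduced genes were examined as a check of the labels. In 29 tests over 12 of the 13 groups, 24 did not pass, 4 were lower in the group that received the gene and 1 was higher. Map3k7 was lower in the MAP3K7 tumours on 3 probe sets, at log2 differences of -0.25, -0.33 and -0.34 from the other 12 groups (SE 0.07, 0.09 and 0.09). Another Map3k7 probe set was higher by 0.16 but lay below the control level, at 2.65. Pip5k1b was lower in the PIP5K1B tumours (log2 difference -0.40, SE 0.12, n = 6). None rose by 2-fold. A human gene, or one without the mouse transcript's end, would not be seen by these probe sets, so they do not check the labels.

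The comparison of MAP3K11 with the other 12 groups asks what sets the tumours labelled with cachexia apart. The chloride channel Cftr (chromosome 6, 18170687 to 18322770 on GRCm38.p6) was at 8.16 ± 0.31 (SD, n = 6) in MAP3K11, a log2 difference of 5.51 ± 0.18 (SE) from the other 12 groups. Ano4 (chromosome 10, 88948932 to 89345205), of a family of calcium-activated channels and scramblases, was higher by 5.80 ± 0.06 (SE), at 8.48 in MAP3K11 against 2.68 on average. The axonal growth protein Gap43 was higher by 5.28 and the neurofilament subunit Nefm by 4.60. The retinal dehydrogenase Aldh1a3 (4.71), the milk protein kappa-casein Csn3 (4.75) and the protease inhibitor Serpinb2 (4.40) rose as well. Aldh1a3 was also at 12.38 and 12.10 in 2 MAP3K7 arrays, above every MAP3K11 array (11.44 to 11.92). On the other side, Macc1 (chromosome 12, 119390398 to 119466934), known as a promoter of metastasis, was at 4.03 ± 0.57 (SD, n = 6) against 9.07 in the other groups, a log2 difference of -5.04 ± 0.35 (SE).

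Of the 13868 genes, 3461 were higher and 4060 lower in MAP3K11, and 803 differed by 2-fold or more. The share of called genes that was higher was 46.0%, and it was 52.4% after quantile normalization and 42.1% after median centring. The other genes named by the rule were Clca3b, Adamdec1 and Nebl among those higher, with differences of 5.15, 4.84 and 4.01. In Clca3b, another chloride channel regulator, the 6 MAP3K11 arrays were far apart (SD 2.56). Among the lower genes were the arginine deiminase Padi4 (-4.93), the synaptic pentraxin Nptx1 (-4.83), the T cell receptor segment Trbv1 (-4.36), Kirrel3 (-3.90), Plxdc1 (-3.65) and the transcription factor Foxf1 (-3.51). Padi4 was as low in 1 pair of ErbB3 arrays (4.18 and 4.57) as in MAP3K11 (4.21 to 4.76). The means of the other groups lay below the control level for Ano4 (2.61 to 2.80) and, apart from MAP3K7, for Cftr, so those folds are bounded by background. Cftr had a mean of 3.17 in MAP3K7, with 4.64 and 3.75 in 2 of its arrays. In those arrays Adamdec1 (10.77 and 10.71) and Clca3b (8.40 and 8.11) lay within the range of MAP3K11.

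**Figure D2:**
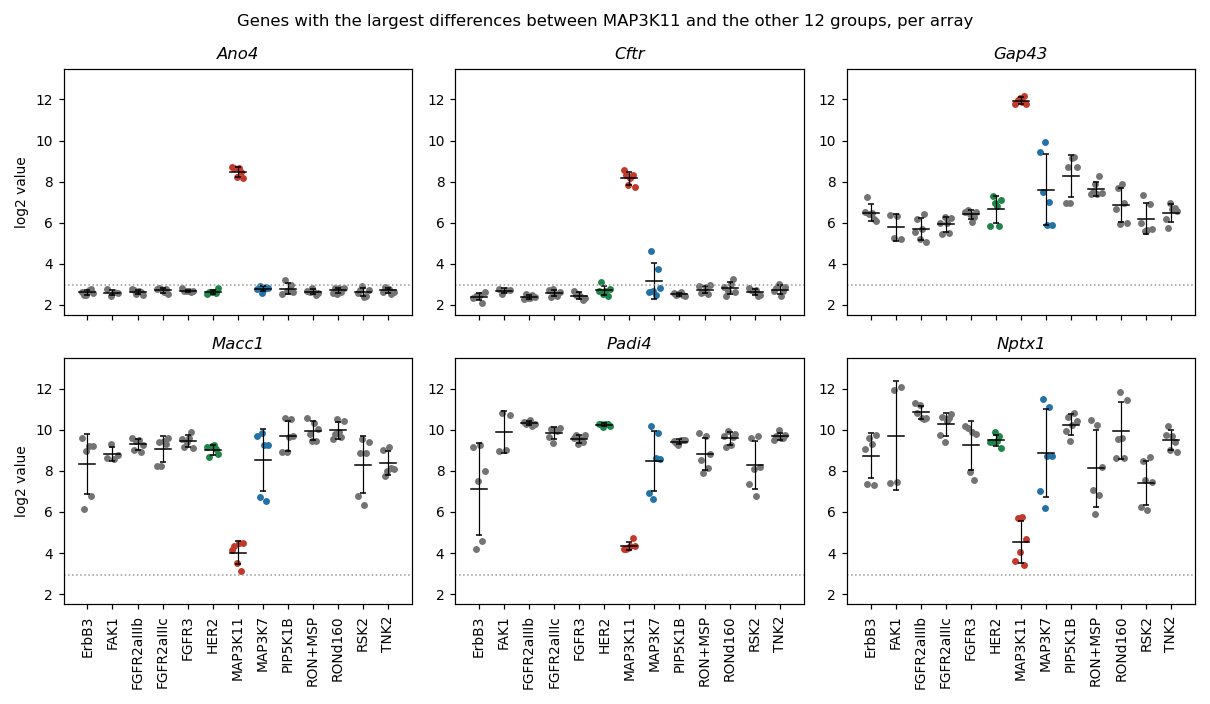
Each point is 1 array and the y axis is its log2 value, for 3 genes higher and 3 lower in MAP3K11 (red); MAP3K7 is blue and HER2 green. Bars are the group mean and SD, and the dotted line is the control level of 2.95; the MAP3K11 means are 8.48 (Ano4), 8.16 (Cftr), 11.93 (Gap43), 4.03 (Macc1), 4.35 (Padi4) and 4.55 (Nptx1).

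Of 30 gene lists fixed before the data were examined, 8 differed between MAP3K11 and the other 12 groups by camera, and none held with an estimated correlation between genes. Where 1 count is given for a list here and in the other comparisons, it was the same adjusted over the list alone. Class II antigen presentation, the machinery that shows peptides to helper T cells, was higher: 11 of 12 measured members rose and 1 fell. Its examples were H2-Ab1 (1.64 ± 0.30, SE), H2-Aa (1.54), the invariant chain Cd74 (1.35) and the dendritic cell integrin Itgax (1.58). Camera gave adjusted p = 0.000857, and adjusted p = 0.769 with an estimated correlation. In the list of JNK and AP-1 response genes, the pathway in which MAP3K11 acts, 14 of 26 rose and 4 fell, and 15 rose adjusted over the list alone (adjusted p = 0.0274, and adjusted p = 0.914 with an estimated correlation). The phosphatase Dusp1 rose by 2.30 ± 0.22 (SE), and the matrix-degrading enzymes Mmp9, Mmp13 and Mmp3 by 1.77, 1.51 and 1.21. Endothelial markers were higher in 16 of 21 members, and 17 adjusted over the list alone, with Tie1 at 0.70 and the receptor Kdr at 0.65 (adjusted p = 0.00884, and adjusted p = 0.914 with an estimated correlation). Fibroblast and matrix genes were higher in 11 of 21 members and lower in 2, and 13 rose adjusted over the list alone; Fap was higher by 1.97, Thy1 by 1.58 and the collagen Col1a1 by 0.87. That list had adjusted p = 0.032, adjusted p = 0.914 with an estimated correlation, and lost its call after quantile normalization (adjusted p = 0.0606). Neither the fibroblast nor the endothelial list was highest in MAP3K11. The fibroblast group mean was 0.34 in MAP3K11, 0.47 in MAP3K7 and 0.35 in RON+MSP. Single arrays lay between 0.13 and 0.90 in RSK2 and between -0.03 and 1.07 in ErbB3, beside 0.17 to 0.60 in MAP3K11. Endothelial array means ran from 0.38 to 0.81 in RSK2 and from 0.22 to 0.52 in MAP3K11.

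The lists that were lower in MAP3K11 were those of interferon response, oxidative phosphorylation, ribosomal proteins and skeletal muscle. Of 25 interferon response genes, 18 fell, 19 adjusted over the list alone, among them the guanylate-binding protein Gbp2 (-2.10 ± 0.27, SE), Bst2 (-1.67), the chemokine Cxcl10 (-1.63) and Ifit1 (-1.57). Its adjusted p was 0.003, and adjusted p = 0.914 with an estimated correlation. Low values were not particular to MAP3K11. The list's array means ran from -0.96 to -0.44 there and from -1.48 to 1.95 in the other 70 arrays. Of those, 6 lay below all MAP3K11 arrays. Of 34 genes of oxidative phosphorylation 21 fell, with a list median of -0.15; the complex I subunits Ndufa4, Ndufv2 and Ndufb5 were at -0.56, -0.48 and -0.43. Of 20 ribosomal protein genes 17 fell, with a list median of -0.09. These 2 lists had adjusted p = 0.00039 and 0.000491, and both had adjusted p = 0.769 with an estimated correlation. Among the members taken with the ribosomal list, Mrpl23, of the mitochondrial ribosome, changed most (-0.67 ± 0.04, SE). The list names Rpl23 and not Mrpl23, which was matched through an older symbol and is counted among the 20.

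Skeletal muscle genes fell in 14 of 24 members (15 adjusted over the list alone), with myosin Myh1 at -4.35 ± 0.55 (SE), the muscle enolase Eno3 at -3.92, the muscle actin Acta1 at -3.52 and Tnnc2 at -2.59. The list had adjusted p = 0.0119, and adjusted p = 0.914 with an estimated correlation. With the pairs as a block 3 of its members passed. Muscle content varied between arrays within groups: the list mean, relative to all arrays, spanned -1.66 to 3.65 in the other 70 arrays and -1.64 to -1.45 in MAP3K11. With the muscle mean as a covariate, an alternative chosen after seeing the data, the list was no longer called (adjusted p = 0.304), its median turned to 0.28 and Tnnc2 to 0.17. The covariate is this list's own mean, so the loss of its call was fixed in advance. Eno3 was at 7.65 ± 0.60 (SD, n = 6) in MAP3K11 against 11.57 in the other groups. In 4 MAP3K7 arrays with muscle list means from -1.38 to -0.02, Eno3 lay between 11.02 and 11.59. It was at 8.96 and 9.30 in the other 2, whose muscle means were -1.66 and -1.65. So Eno3 was not low in every array with a low muscle mean. Myh1, at 2.86 in MAP3K11, lay below the control level.

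The list of cachexia-linked secreted factors was not called by camera (adjusted p = 0.428). Of its 23 measured members 9 rose and 5 fell, and its median was 0.02. Milk protein genes were not called either (adjusted p = 0.0977), yet 5 of 9 rose, 1 fell and the list mean of every MAP3K11 array (0.79 to 1.01) lay above that of all other 70 arrays, of which the highest was at 0.36. Csn3, named above among the genes with the highest differences, is 1 of the 9 and weighs heavily on that mean. Macrophage genes fell in 9 of 22 members and none rose (adjusted p = 0.115 for the list). Proliferation genes fell in 13 of 30 and rose in 2, and 12 fell adjusted over the list alone (adjusted p = 0.376 for the list).

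**Figure D3:**
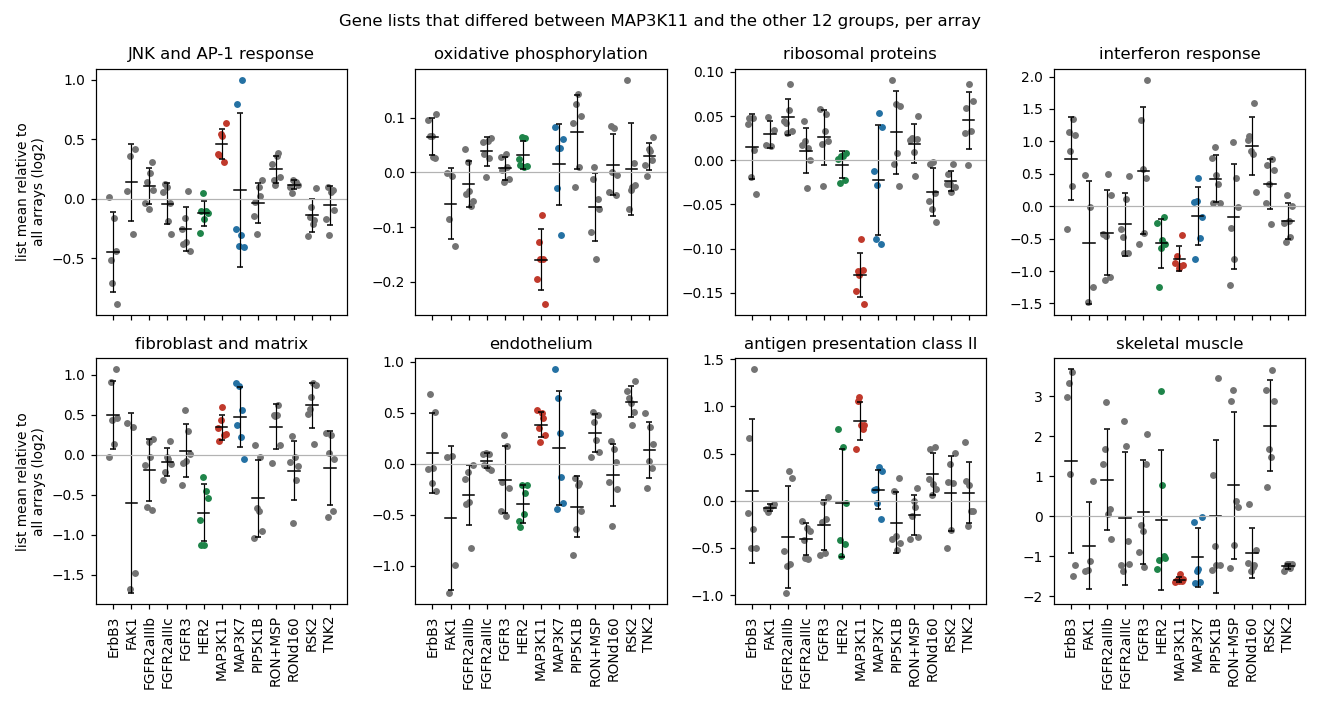
Each point is 1 array; the y axis is the mean log2 value of a gene list relative to the mean of all arrays, for the 8 lists that camera called for MAP3K11 (red) against the other groups, with MAP3K7 in blue and HER2 in green. Bars are the group mean and SD; the MAP3K11 arrays span -0.16 to -0.09 in ribosomal proteins, with 68 of the other 70 arrays above them, and -1.64 to -1.45 in skeletal muscle.

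MAP3K11 and MAP3K7 are the genes that the design text names as tested, both kinases of the same family. The neurofilament subunit Nefm (chromosome 14, 68119545 to 68125004) was higher by 5.40 ± 0.52 (SE) in MAP3K11, at 9.19 ± 0.71 against 3.79 ± 0.24 (SD, n = 6 each), and Nefl by 4.19. Ano4 (5.69), Cftr (4.99), Serpinb2 (5.21), Gap43 (4.32), Csn3 (3.87), Plet1 (3.99), the epithelial protease Tmprss11e (5.04) and Adamdec1 (4.36) were higher too. Lower were Macc1 (-4.51 ± 0.47, SE), Nptx1 (-4.34), Padi4 (-4.11), Kirrel3 (-4.06), Foxf1 (-3.52), Plxdc1 (-3.17), Eno3 (-2.94), the adenylate kinase Ak5 (-3.09), the potassium channel subunit Kcnf1 (-2.97) and Ogn (-3.55), a proteoglycan of connective tissue. In all, 5189 genes differed, 2299 higher (44.3%) and 2890 lower in MAP3K11, and 2996 with the pairs as a block; 52.2% were higher after quantile normalization and 44.7% after median centring.

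Camera called 9 lists in this comparison, and with an estimated correlation each had adjusted p = 0.924. Class II antigen presentation was higher in 8 of 12 members and lower in 1 (10 higher adjusted over the list alone), with Cd80 at 1.37 and Itgax at 1.17. JNK and AP-1 genes rose in 11 of 26 and fell in 2, with Dusp1 at 1.67 ± 0.30 (SE), Egr2 at 1.26 and the urokinase receptor Plaur at 1.23; its call ended after quantile normalization (adjusted p = 0.0675). Fatty acid and sterol synthesis was higher in 14 of 26, with the sterol enzymes Dhcr7 at 1.32 and Hsd17b7 at 1.08. Milk protein genes rose in 5 of 9 and fell in 1 (6 higher adjusted over the list alone), Btn1a1 by 3.67 ± 0.33 (SE), and this call too ended after quantile normalization (adjusted p = 0.0675). Proliferation genes rose in 14 of 30, and 16 adjusted over the list alone, with Aurka at 0.89 and Rrm2 at 0.64.

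Oxidative phosphorylation fell in 17 of 34 members (18 adjusted over the list alone), ribosomal proteins in 7 of 20, interferon response in 5 of 25, and macrophage and monocyte genes in 10 of 22 (11 adjusted over the list alone), Ms4a7 by 1.55 and Cd68 by 0.96 on the log2 scale. For these 4 lists too, adjusted p = 0.924 with an estimated correlation. The array means of the class II and milk lists were apart between the groups, and those of the other 7 called lists overlapped. The macrophage means were 0.80 and 0.81 in 1 pair of MAP3K7 arrays and between -0.33 and -0.07 in the other 4, beside -0.55 to -0.16 in MAP3K11. The array MAP3K7 T1 replicate 2 and the array MAP3K7 T3 replicate 1 formed another of the pairs and lay apart from the other 4 MAP3K7 arrays; Adamdec1, for example, was at 10.77 and 10.71 in them and between 4.02 and 5.10 in the others. Without those 2 arrays 5542 genes differed, the proliferation list lost its call and turned to a median of -0.05 (adjusted p = 0.952), and the milk list lost its call (adjusted p = 0.0793). The JNK and AP-1 means of those arrays (0.80 and 1.00) lay above all MAP3K11 arrays (at most 0.63) and those of the other 4 at -0.25 or below; without them that list's median was 0.62 (adjusted p = 9.06e-05). In the interferon, ribosomal and oxidative phosphorylation lists the overlap came only from those arrays. The other 4 were at -0.16, -0.03 and 0.04 or higher in these lists, above all MAP3K11 arrays (at most -0.44, -0.09 and -0.08). Leaving out those 2 arrays was chosen after seeing the data.

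The comparison of MAP3K11 with HER2 sets it against the oncogene that drove the parental model. Aldh1a3 (chromosome 7, 66390892 to 66427477) was at 11.65 ± 0.21 in MAP3K11 and 5.16 ± 0.54 in HER2 (SD, n = 6 each), a log2 difference of 6.49 ± 0.79 (SE). Ano4 (5.84), Cftr (5.45), Gap43 (5.28) and Clca3b (5.26) were also higher. Padi4 was lower by a log2 difference of -5.89 ± 0.51 (SE), and so were Trbv1 (-5.01), Macc1 (-5.00), Nptx1 (-4.94) and the proton channel Otop1 (-4.81). In all 6826 genes differed, 2982 higher (43.7%) and 3844 lower in MAP3K11, and 4621 with the pairs as a block; 51.2% were higher after quantile normalization and 37.3% after median centring.

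Camera called 11 lists, and the medians were 1.01 for fibroblast and matrix genes, 0.85 for class II genes and 0.80 for endothelium. Fibroblast and matrix genes rose in 15 of 21 and fell in 1 (16 rose adjusted over the list alone), Fap by 2.74 ± 0.29 (SE) and the receptor Pdgfrb by 2.41, and endothelial genes rose in 18 of 21, Kdr by 1.17. Class II genes rose in 10 of 12, but their means in 1 pair of HER2 arrays (0.57 and 0.76) lay within the range of MAP3K11 (0.54 to 1.10), and in the other 4 at -0.02 or below. These 3 lists had adjusted p = 0.599 with an estimated correlation. Killer cell and T cell genes rose in 6 of 12, the granzyme Gzmb by 2.38 and Gzma by 1.96, and B and plasma cell genes in 4 of 12 (3 adjusted over the list alone), Irf4 by 0.88; both had adjusted p = 0.599 with an estimated correlation and lost their calls after quantile normalization (adjusted p = 0.0818 and 0.103), the second also with the pairs as a block (adjusted p = 0.0608). JNK and AP-1 genes rose in 14 of 26 and fell in 2, Dusp1 by 2.75 ± 0.30 (SE), with adjusted p = 0.633 for the list with an estimated correlation. Relative to all arrays, the HER2 means of the fibroblast, endothelial, and killer and T cell lists were -0.72, -0.39 and -0.50. Those of MAP3K11 were 0.34, 0.39 and 0.21, so these differences lie partly in HER2.

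Genes of the amino acid and ATF4 stress response fell in 16 of 28, the serine synthesis enzymes Phgdh and Psat1 by 1.58 each on the log2 scale, and that list had adjusted p = 0.633 with an estimated correlation. Its mean, relative to all arrays, was 0.46 in HER2 and -0.11 in MAP3K11. It was not among the 8 lists called for MAP3K11 against the other 12 groups, so this difference lies largely in HER2. Hypoxia and glycolysis genes were lower in 16 of 30 and higher in 4 (18 and 5 adjusted over the list alone); Car9 was at -3.72 ± 0.55 (SE) and Egln3 at -3.51. Proliferation genes were lower in 16 of 30 and higher in 1. The array means of the hypoxia list overlapped between the groups, as did those of the class II list, and those of the other 9 called lists were apart. The hypoxia and proliferation lists had adjusted p = 0.931 with an estimated correlation, and both lost their calls under either rescaling of the arrays (adjusted p between 0.0535 and 0.0782), and the hypoxia list also with the pairs as a block (adjusted p = 0.074) and with the muscle mean as a covariate (adjusted p = 0.0587). Oxidative phosphorylation fell in 23 of 34 and ribosomal proteins in 13 of 20, each with adjusted p = 0.599 with an estimated correlation; the ribosomal call ended after quantile normalization (adjusted p = 0.0837).

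MAP3K7 was also compared with HER2. MAP3K7 tumours held more of the matrix proteoglycan Ogn (chromosome 13, 49608015 to 49624501; 4.33 ± 0.79, SE; 10.33 ± 1.64 against 5.99 ± 1.03, SD, n = 6 each) and the integrin Itga8 (3.03), and of the granzymes Gzmc (3.35) and Gzmf (3.12), proteases of killer cells. They held less of the tight junction protein Cldn6 (-3.48 ± 0.64, SE), of Tmprss11e (-4.19) and Wfdc2 (-3.09), and of Otop1 (-4.80) and Pbp2 (-3.00). Aldh1a3 was higher by 3.90, and by 2.27 without the 2 MAP3K7 arrays that lay apart. In all 5056 genes differed, 2277 higher (45.0%) and 2779 lower in MAP3K7, and 2531 with the pairs as a block; 47.8% were higher after quantile normalization and 35.8% after median centring.

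Proliferation genes fell in 28 of 30 members, and 29 adjusted over the list alone, with a median of -0.67; Ccne2 was at -1.18 ± 0.20 (SE), Bub1 at -0.90 and Kif11 at -0.87. The list had adjusted p = 2.36e-12, and adjusted p = 0.469 with an estimated correlation. Without the 2 arrays that lay apart its median was -0.25 and the call held (adjusted p = 0.000124). Amino acid and ATF4 stress genes fell in 22 of 28, Trib3 by 2.07, Chac1 by 2.03 and Psat1 by 1.44 on the log2 scale, and sterol and fatty acid synthesis in 18 of 26 (21 adjusted over the list alone), Fdps by 1.05 and Idi1 by 0.96. Both had adjusted p = 0.469 with an estimated correlation. Hypoxia and glycolysis genes fell in 18 of 30 and rose in 2 (19 fell adjusted over the list alone), Car9 by 2.60, with adjusted p = 0.615 with an estimated correlation. Targets of p53 fell in 9 of 21 and rose in 3 (10 and 4 adjusted over the list alone), Ccng1 by 0.93 and Cdkn1a by 0.88, with adjusted p = 0.519 with an estimated correlation; that call ended after median centring (adjusted p = 0.0565).

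Fibroblast and matrix genes rose in 16 of 21, Pdgfrb by 2.40 ± 0.32 (SE), Pdgfra by 2.32 and Postn by 1.45, and genes of the epithelial-mesenchymal transition rose in 9 of 22 and fell in 2, the repressor Snai2 by 1.76 and Mmp2 by 1.68. Both had adjusted p = 0.469 with an estimated correlation. Endothelial genes rose in 12 of 21 (14 adjusted over the list alone) and macrophage genes in 8 of 22, Ms4a7 by 1.96 and Apoe by 1.60; these lists had adjusted p = 0.615 and adjusted p = 0.7 with an estimated correlation. Killer cell and T cell genes rose in 7 of 12, Gzmb by 2.29 and Nkg7 by 1.19, with adjusted p = 0.519 with an estimated correlation. Relative to all arrays, the HER2 means of the ATF4 stress, fibroblast, and killer and T cell lists were 0.46, -0.72 and -0.50. Those of MAP3K7 were -0.33, 0.47 and 0.27, so these differences lie partly in HER2. The array means overlapped between the groups in the endothelial, macrophage, hypoxia, p53 and epithelial-mesenchymal lists. The endothelial means were 0.65 and 0.93 in 1 pair of MAP3K7 arrays and between -0.44 and 0.30 in the other 4, beside -0.62 to -0.21 in HER2. The macrophage means were 0.80 and 0.81 in another pair and between -0.33 and -0.07 in the other 4, beside -0.64 to -0.23 in HER2.

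FGFR2aIIIb and FGFR2aIIIc are splice forms of 1 receptor with different ligand-binding ends. Few genes separated them. The dual-specificity kinase Dyrk1a (chromosome 16, 94569947 to 94695519) was higher in FGFR2aIIIb by 0.57 ± 0.12 (SE), at 8.07 ± 0.13 against 7.50 ± 0.10 (SD, n = 6 each), and the carbonyl reductase Cbr1 was lower (-1.08 ± 0.20, SE), as was Ptprn2 (-1.67). Pogz (0.51), Sec24a (0.42), Wdr77 (0.41) and Nfx1 (0.37) were the other named genes that were higher, and Apobr (-1.03), Dleu2 (-0.97) and Fam111a (-0.97) those that were lower. The water channel Aqp8, chosen after its values were seen, was higher by 1.21 ± 0.21 (SE). In all 23 genes differed, 9 higher (39.1%) and 14 lower; the share that was higher was 28% of 25 genes after quantile normalization and 50% of 14 after median centring.

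With the pairs as a block limma called 0 genes (530 at an unadjusted p under 0.05), and none of the 10 named genes passed. With the replicates of a group numbered 1 to 6 across T labels, leaving out FGFR2aIIIb replicate 1, 2, 4, 5 or 6 gave 15, 8, 8, 7 or 10 genes, and leaving out FGFR2aIIIc replicate 1, 2, 3 or 4 gave 5, 42, 10 or 11. Camera called 6 lists, in which limma called 0 members: ERK feedback, ribosomal proteins and skeletal muscle with medians of 0.18, 0.03 and 1.15, and oxidative phosphorylation, endothelium, and B and plasma cells with medians of -0.05, -0.34 and -0.16. Each had adjusted p = 0.971 with an estimated correlation, and the array means of all 6 overlapped between the groups. After quantile normalization the ribosomal and B cell calls ended (adjusted p = 0.549 and 0.101), and after median centring that of oxidative phosphorylation (adjusted p = 0.111). Muscle genes varied widely within both groups, and with the muscle mean as a covariate that list's median was 0.02 (adjusted p = 0.938). The covariate is that list's own mean, so this loss was fixed in advance.

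RONd160, by its name a deletion form of RON, was compared with RON given together with its ligand MSP. The interferon-induced protease Usp18 (chromosome 6, 121245906 to 121270917) was higher by 2.04 ± 0.45 (SE) in RONd160, at 9.66 ± 0.55 against 7.66 ± 1.03 (SD, n = 6 each), Mx1 by 1.83, Cxcl10 by 1.81 and Ifit1 by 1.76, and the tryptophan-degrading enzyme Ido1 by 2.79. Of the 25 interferon genes 14 rose, 22 adjusted over the list alone, with a median of 1.00 (adjusted p = 3.43e-11, and adjusted p = 0.681 with an estimated correlation). With the pairs as a block no member passed. The list's array means ran from 0.21 to 1.59 in RONd160 and from -1.22 to 1.00 in RON+MSP, where 1 pair was at -1.22 and -0.82 and another at 1.00 and 0.43. Tmprss11e (5.49), the folate enzyme Aldh1l1 (2.34) and the arginine deiminase Padi3 (1.97) were higher as well, and the matrix protein Thbs4 (-3.63), Cavin4 (-1.94), Epb41l4a (-1.84), the receptor Epha3 (-1.68) and Gabbr1 (-1.67) were lower. Of these, Tmprss11e, Ido1, Aldh1l1, Padi3 and Gabbr1 passed with the pairs as a block.

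In all 1700 genes differed, 852 higher (50.1%) and 848 lower, 201 with the pairs as a block and 1106 without RONd160 replicate 6; 55.8% were higher after quantile normalization and 40.4% after median centring. Camera called 12 lists, and the array means overlapped between the groups in all but the B and plasma cell list. Sterol and fatty acid synthesis was higher in 4 of 26 (6 adjusted over the list alone), with the regulator Srebf2 at 0.50, oxidative phosphorylation in 10 of 34 with 1 lower (13 higher adjusted over the list alone), and B and plasma cell genes in 2 of 12. Genes of the unfolded protein response were lower in 8 of 21 (9 lower and 2 higher adjusted over the list alone), with the chaperone Hsp90b1 at -0.34, endothelial genes in 4 of 21 (8 adjusted over the list alone), with Kdr at -0.71, fibroblast genes in 2 of 21, with Pdgfrb at -1.40, genes of the epithelial-mesenchymal transition in 2 of 22 (4 adjusted over the list alone) and ribosomal proteins in 3 of 20. With an estimated correlation, the B and plasma cell list had adjusted p = 0.613 and the other 7 of these had adjusted p = 0.681. Of the members of these 8 lists, Atp5d, Rps18 and Pdgfrb alone passed with the pairs as a block. The class II, adipocyte and skeletal muscle lists were called with 0 members passing by limma, at medians of 0.44, 0.43 and -1.77 and, with an estimated correlation, adjusted p = 0.698, 0.811 and 0.681. The ribosomal and adipocyte calls ended after quantile normalization (adjusted p = 0.132 and 0.0682), the adipocyte call also with the pairs as a block (adjusted p = 0.105), and with the muscle mean as a covariate those of the class II, adipocyte and skeletal muscle lists (adjusted p = 0.0645, 0.242 and 0.958). For the skeletal muscle list that loss was fixed in advance, since the covariate is its own mean.

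For the T labels, limma called 0 genes in T2 against T1 (306 at an unadjusted p under 0.05) and 0 in T3 against T1 (654 unadjusted, lowest adjusted p = 0.816). With the pairs as a block it called 0 (1006 unadjusted) and 1 (1440 unadjusted), Spryd4, chosen after its values were seen, at -0.14 ± 0.03 (SE). In all 38 pairs the T labels differ. The fit without the block leaves the differences between pairs in the spread, which makes it the weaker test of T. Camera called 11 lists for T2 and 10 for T3, in none of which a member passed, and 7 and 9 were called with the pairs as a block. The largest medians were those of skeletal muscle (0.43) and fibroblast and matrix genes (0.19) in T2, and of interferon response (0.29), hypoxia and glycolysis (0.16) and proliferation genes (-0.11) in T3. With an estimated correlation the lowest adjusted p was 0.672 for T2 and 0.51 for T3. In data simulated with independent arrays and 100 genes changed by 1 log2 unit, 96 were recovered for T3 against T1. That recovery does not cover paired arrays.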

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

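The tests of the pairs, of the pairs as a block, of the founder line, of a wrong label and of other cell types were chosen only after the result was seen, and so was the muscle covariate as an alternative, while its bound and the tests of other splits were set before.

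Of 447 groups of values examined for 1 array apart from the rest, 14 held one, and chance gives about 1 in 20, or 22.35. In MAP3K11, Padi4 was highest in T3 replicate 1 (4.76, next 4.36), Ndufb5 lowest in T3 replicate 2 (10.40, next 10.66) and Cel highest in T2 replicate 2 (5.47, next 4.70). The interferon list mean was highest in MAP3K11 T3 replicate 1 (-0.44, next -0.77), and the sterol and fatty acid list mean lowest in MAP3K11 T3 replicate 2 (-0.30, next 0.05). RONd160 T1 replicate 3 was lowest for Epha3 (3.53, next 5.08), Pdgfrb (9.07, next 9.70) and Flt1 (7.31, next 7.65), and RONd160 T3 replicate 2 was highest for Dhcr7 (7.02, next 6.88). In HER2, T2 replicate 1 was highest for Psph (9.81, next 9.71) and Ndufb5 (11.20, next 11.06), T1 replicate 1 highest for Ccne2 (8.09, next 7.65), T1 replicate 2 lowest for Chac1 (8.08, next 9.19) and T3 replicate 1 highest for Nkg7 (4.69, next 4.44).

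The difference of MAP3K11 from the other groups changed with the T label in 3 genes by limma's test of the interaction, chosen after their values were seen. Calcb, a calcitonin gene-related peptide, was higher by 1.52, 3.17 and 1.49 at T1, T2 and T3 (adjusted p = 0.0034), the chemokine Ccl22 by 0.21, 1.42 and 1.44 (adjusted p = 0.0034) and Gp2 by 0.56, 1.87 and 0.85 (adjusted p = 0.0296). Each difference rests on 2 MAP3K11 arrays at each T label. Among 4717 probe sets that name no single gene, which the comparisons leave aside, 2118 (44.9%) differed between MAP3K11 and the other groups, 1004 higher and 1114 lower.

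The arrays of an introduced gene fell into pairs that span T labels. Matching them on expression with the chromosome medians removed gave 36 of the 38 pairs found from the chromosome medians, against at most 20 in random matchings, which is consistent with 2 arrays from 1 founder line with its own chromosome dosage. In 20 of the pairs the skeletal muscle list's mean differed by over 2-fold, which argues against the same RNA on both arrays of every pair. The T label as a batch would put pairs on 1 label, and 0 were, below the lowest of the random matchings (1). Animals or hosts that were shared within a pair were not tested and stay open. Arrays of different pairs could be as alike in their chromosome medians, at up to 0.929 in FGFR3, where the lowest pair was at 0.873. Between arrays of different introduced genes the highest value was 0.937, so a high value alone cannot identify a founder line. Whether arrays so alike share a line was not tested, and the block counts them as separate.

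MAP3K11 differed from the rest in more genes than any other group did. With the pairs as a block it differed in 5455 and the next group, ErbB3, in 1653, which argues against the counting of paired arrays as separate replicates as the whole source. With the muscle mean as a covariate it differed in 7272, which argues the same against skeletal muscle in the other tumours. Whether its 6 arrays may come from 1 founder line cannot be told apart from an effect of the introduced gene: between its 3 pairs the chromosome medians correlated at a median of 0.401 (-0.28 to 0.73), overlapping the values within pairs (0.473 to 0.951). Cachexia, the introduced gene and any founder are confounded in this group, so the biological explanation stays open too.

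The arrays MAP3K7 T1 replicate 2 and T3 replicate 1 lay apart from the other 4, with higher means of the JNK and AP-1 list (0.80 and 1.00, against at most -0.25) and the ERK feedback list (0.49 and 0.50, against at most -0.45) and lower proliferation means (-0.98 and -1.37, against -0.25 or higher). Over the 803 genes that set MAP3K11 apart by 2-fold or more, their median positions from 0 (the other groups) to 1 (MAP3K11) were 0.533 and 0.492. These lay below the lowest MAP3K11 array (0.956) and above the other 4 (at most 0.101). The genes and the scale were taken from the MAP3K11 arrays themselves, which places those near 1. So the test cannot exclude a MAP3K11 tumour from another founder line under a wrong label. The bound of this test was set after the value was seen, and an earlier bound, at the midpoint of the scale, did not decide. Of 10 lists of other cell types, 0 were higher in both arrays than in the other 4 and 4 were lower in both. The other 4 differed among themselves, from -0.06 to 0.90 in fibroblast and matrix genes and from -0.16 to 0.81 in T and NK cells. The 2 arrays lay between, at 0.36 and 0.55 and at 0.22 and 0.31. A rise over only some of the 4 would be missed, so the test does not decide on fewer tumour cells as the source. Nefm and Ano4, at 8.16 or higher in each MAP3K11 array, were at most at 3.76 and 2.92 in these arrays. Adamdec1 (10.77 and 10.71) and Clca3b (8.40 and 8.11) lay within the MAP3K11 range there, and Aldh1a3 (12.38 and 12.10) above it. The low Nefm and Ano4 argue against a mixture with material like the labelled MAP3K11 arrays. A separate founder line for these MAP3K7 arrays, which form 1 of the pairs, stays open.

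Among 100 splits that take each array as separate, only the real one (1 of 100) gave as many genes in each comparison of groups. That excludes chance only if the arrays are separate, and paired arrays are not. Splits of whole pairs between 2 groups are too few for a share under 0.05, and splits of whole pairs over all 13 groups were not run. The real counts and the highest of the other splits were 7521 and 1059 for MAP3K11 against the other groups, 5189 and 3607 against MAP3K7, and 6826 and 4244 against HER2. They were 5056 and 2895 for MAP3K7 against HER2, 1700 and 474 for the RON forms, and 11916 and 11 for the 13 groups. For the FGFR2 forms they were 23 and 9. Simulated arrays with correlated pairs and no change gave 159 calls there. With the pairs as a block limma called 0 (530 at an unadjusted p under 0.05), so chance is not excluded for the FGFR2 forms. For T2 and T3 against T1 limma called 0 genes (306 and 654 at an unadjusted p under 0.05), so all 100 of 100 splits had to give as many and say nothing about chance; the highest other split gave 1.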

How the results depend on the processing

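The pairs as a block, the muscle covariate and leaving out the 2 MAP3K7 arrays were chosen after the result was seen. MAP3K11 ranked 1 among the 13 groups under all 16 settings in which the rank was computed. Of 256 counts under alternatives, 214 stayed within 1.5 times the reported one; of 7936 values of named genes, 7373 kept their direction and call, 561 kept the direction without the call and 2 turned. Of 803 list values 682 kept both, 118 lost the call and 3 turned. The report names the list calls that ended with quantile normalization, median centring, the pairs as a block, the muscle covariate or without the 2 MAP3K7 arrays. The mean of probe sets ended 7: interferon in MAP3K11 against MAP3K7, proliferation, T and NK cells and B cells in MAP3K11 against HER2, oxidative phosphorylation in the FGFR2 forms, and oxidative phosphorylation and class II in the RON forms. The stricter filter ended 6: interferon and milk in MAP3K11 against MAP3K7, proliferation, hypoxia and B cells in MAP3K11 against HER2, and B cells in the FGFR2 forms. Each of the following ended the calls named: no filter, JNK and AP-1 in MAP3K11 against MAP3K7 and adipocyte in the RON forms; array weights, proliferation and milk in MAP3K11 against MAP3K7; means for each gene and T label, p53 targets in MAP3K7 against HER2 and B cells in the FGFR2 forms; and no T term, adipocyte in the RON forms. The cause was not tested unless given.

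Testing every probe set by itself gave 13731 for MAP3K11 against the other groups, 9205 against MAP3K7, 12453 against HER2, 9026 for MAP3K7 against HER2, 2950 for the RON forms and 21514 for the 13 groups, since more features are tested. Asking for 2-fold as well gave 803, 660, 1057 and 565 in the first 4, 4 for the FGFR2 forms and 80 for the RON forms, and an adjusted p under 0.01 gave 3238 for MAP3K7 against HER2, 6 for the FGFR2 forms and 651 for the RON forms, by construction. With only the 2 groups compared these last 3 counts were 3114, 51 and 565. T1, T2 or T3 arrays alone, with 2 MAP3K11 arrays each, gave 2959, 2673 and 2666 for MAP3K11 against the other groups.

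With the pairs as a random block the counts were 2996 for MAP3K11 against MAP3K7, 2531 for MAP3K7 against HER2 and 0 for the FGFR2 forms (530 unadjusted). They were 201 for the RON forms and 7495 for the 13 groups. These counts fell, since paired arrays then add less. For T3 against T1, where the labels differ within the pairs, the count was 1, against 0 without the block. The named genes that lost their call were 10 of 10 for the FGFR2 forms, 30 of 38 for the RON forms, 8 of 55, 3 of 54 and 2 of 49 for MAP3K11 against MAP3K7, HER2 and the other groups, and 6 of 49 for MAP3K7 against HER2. With the replicate number as a block the counts were 7495, 5182, 6837, 5051, 10 and 1603 in the order of the comparisons, 11877 for the 13 groups and 0 for both T comparisons by limma. Replicate numbers do not pair the arrays: over 370 array pairs of different groups with 1 T label and number the median r was -0.01.

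The FGFR2 count was also 15 without the filter, 14 after median centring, 5 with the mean of probe sets and 405 with array weights. Leaving out 1 replicate gave 5 to 42 for it, 1106 to 1687 for the RON forms, 6862 to 7193 for MAP3K11 against the other groups, 4591 to 5276 against MAP3K7, 6335 to 6691 against HER2 and 4453 to 5000 for MAP3K7 against HER2. Without the 2 MAP3K7 arrays, MAP3K11 against MAP3K7 gave 5542 and MAP3K7 against HER2 4377.

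In RONd160 against RON+MSP, Sdhd turned from 0.22 to -0.087 with the mean of probe sets. With the muscle covariate Tnnc2 in MAP3K11 turned from -2.59 to 0.17 and the skeletal muscle list from -1.58 to 0.28, and in the RON forms from -1.77 to 0.010, since the covariate is that list's mean. The proliferation list of MAP3K11 against MAP3K7 turned from 0.31 to -0.047 without the 2 arrays. Quantile normalization and median centring shifted the median change of all probe sets in MAP3K11 against the other arrays by -0.01 and -0.02. The floors planned for linear values did not apply, as the values are log2; with no block in the fit, the alternative without one was the same fit; and the alternatives for the gene in the series title were not run. Genes near the control level, such as Ano4 outside MAP3K11, Cftr outside MAP3K11 and MAP3K7, and Myh1 in MAP3K11, have folds bounded by background.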

Other observations

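The comparisons of each other group with the remaining 12 were computed to rank the groups, and their genes and lists, chosen after their values were seen, are given as values. ErbB3 tumours held less of the keratin Krt18 (-3.63 ± 0.43, SE; 8.63 ± 2.51, SD, n = 6, against 12.20) and the tight junction protein Cldn6 (-3.06), and more of the cartilage collagen Col10a1 (3.04), the growth factor Ptn (2.68) and the matrix protein Mgp (2.61). Hypoxia and glycolysis genes fell in 24 of 30 members there and rose in 2 (25 and 2 adjusted over the list alone), and ERK feedback genes fell in 13 of 18, the same adjusted over the list alone. Camera gave adjusted p = 5.58e-12 and 9.78e-07, and adjusted p = 0.446 for both with an estimated correlation. Interferon response genes rose in 19 of 25 in ErbB3 (21 adjusted over the list alone; adjusted p = 9.78e-07, and adjusted p = 0.673 with an estimated correlation), with 4 called with the pairs as a block. In ErbB3, 1 pair of arrays differed from the other 4 arrays in these lists, with hypoxia means of -0.12 and 0.04, ERK feedback means of -0.05 and -0.13 and interferon means of -0.35 and 0.30. The fibroblast and matrix means were also lower in this pair (-0.03 and 0.13, against 0.43 to 1.07), and so were the T and NK cell means (-0.46 and -0.15, against 0.13 to 1.16). In RONd160 interferon response genes rose in 20 of 25 (21 adjusted over the list alone), and 14 were called with the pairs as a block; Ido1 was higher by 2.61 ± 0.27 (SE), Usp18 by 2.12 and Ifit3 by 2.07 (adjusted p = 8.26e-12 for the list, and adjusted p = 0.644 with an estimated correlation).

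In RSK2, skeletal muscle genes rose in 22 of 24 (24 adjusted over the list alone), Tnnc2 by 4.06 ± 0.98 (SE), Acta1 by 3.32 and Ckm by 3.19, with adjusted p = 9.7e-17 for the list and adjusted p = 0.552 with an estimated correlation; with the pairs as a block limma called 0 members. Endothelial genes rose there in 18 of 21 (19 adjusted over the list alone), and 12 were called with the block (adjusted p = 5.23e-16, and adjusted p = 0.538 with an estimated correlation). Fibroblast and matrix genes rose with them in 9 of 21 (17 adjusted over the list alone), 2 with the block (adjusted p = 1.32e-08, and adjusted p = 0.552 with an estimated correlation). In HER2, amino acid and ATF4 stress genes rose in 20 of 28 (22 adjusted over the list alone) and fibroblast and matrix genes fell in 16 of 21 (18 adjusted over the list alone), with adjusted p = 3.58e-09 and 1.56e-09 and both with adjusted p = 0.501 with an estimated correlation, and the water channel Aqp5 was higher by 2.81 ± 0.40 (SE). The endothelial, macrophage, and T and NK cell lists were lower in HER2 too, with group means of -0.39, -0.38 and -0.50 and every array below 0. Camera gave these 3 adjusted p = 4.6e-06, 6.82e-05 and 0.00351, and adjusted p = 0.609, 0.609 and 0.577 with an estimated correlation. In MAP3K7, proliferation genes fell in 29 of 30, also adjusted over the list alone, and 26 were called with the block (adjusted p = 4.45e-20, and adjusted p = 0.524 with an estimated correlation). The list's means were -0.98 and -1.37 in the pair of MAP3K7 arrays that lay apart and between -0.25 and -0.03 in the other 4. Genes of the unfolded protein response rose in 11 of 21 in RON+MSP (17 adjusted over the list alone), 4 of them with the block, with adjusted p = 5.6e-16 and adjusted p = 0.0517 with an estimated correlation.

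The receptor Glp1r was higher in PIP5K1B tumours by 2.55 ± 0.25 (SE), while Crip2, a LIM domain protein, was at -2.13 ± 0.15 and the annexin Anxa8 at -2.67. FGFR2aIIIb tumours held more of Otop1 (4.01 ± 0.50, SE), Clca3a1 (3.59) and Cldn6 (2.92) and less of the growth factor Hgf (-1.93). In TNK2 the homeobox gene Hoxa5 was higher by 1.81 ± 0.28 (SE) and the protease Adamts8 by 1.35. These genes passed with the pairs as a block as well. In FAK1, with 4 arrays, endothelial genes fell in 11 of 21 members (18 adjusted over the list alone), with adjusted p = 1.22e-08 and adjusted p = 0.753 with an estimated correlation, and with the block limma called 0 of them. The list's means were -1.27 and -0.99 in 1 pair of FAK1 arrays and 0.07 and 0.08 in the other. In the first pair the fibroblast and matrix means (-1.67 and -1.48), the macrophage means (-1.05 and -0.75) and the interferon means (-1.48 and -1.24) lay below those of the other pair too.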
